A study of Pseudarthrobacter chlorophenolicus A6 with 14 samples.

How the data were processed

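RNA came from cultures of Pseudarthrobacter chlorophenolicus A6 grown, per the labels, at 28 °C with shaking at 180 rpm to an OD600 of 0.2, in a minimal medium (GM) that held 0.1% of yeast extract. A volume of 10 ml of culture was mixed with 10 ml of medium, with or without NaCl or PEG8000, and after 30 min the cells were collected on a 0.2 µm filter and frozen. RNA was extracted with acid phenol and labelled as cDNA with the dye Cy3, per the labels. The labels describe replicates as independent; 4 solute controls, 4 NaCl arrays, 4 matric controls and 2 PEG arrays were analysed here. Sample groups and replicate numbers were taken from the sample titles.

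The arrays were single-colour Agilent arrays. Spot intensity values were made by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers; the processed signal is the background-subtracted and spatially detrended intensity of a spot on a linear scale, with no scaling between arrays. Each array held 14125 spots, of which 536 were control spots and 13589 were probes with 1 spot each. Of the 4632 feature names, 4400 had 3 probes, 157 had 2 and 75 had 1. They comprise 4622 numbered locus tags, 3 tags with an R before the number and 7 features named for the reporters GFP, LuxAB and echerry. The authors' deposited value table holds log2 values for 3994 tags, each gene centred on its median over the 14 arrays. Its columns correlated at 0.876 to 0.987 with the values computed here after the same centring, in the same direction, with slopes of 0.738 to 0.973 and column medians of -0.009 to 0.010. How the authors scaled arrays to each other is not given in the sources used here.

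The processed signal was taken to log2 and the 75th percentile over all probes of the array was subtracted. Values flagged as non-uniform or population outliers (212 values, 0.111%) were left out, and no spot was saturated. A probe was kept where it was well above background on all arrays of at least 1 group, which kept 13578 probes and 4630 features. The background mark was lenient, since most reporter features also passed it. Probes of a feature were averaged on the log2 scale. Signals were far above the negative control spots, with the median probe at 140 to 287 times their median.

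Contrasts were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, in a fit of all 14 arrays with 4 groups, which has 10 residual degrees of freedom and lets the groups share an estimate of the spread. Benjamini-Hochberg adjustment was applied over the 4630 features, and features under 0.05 were called. The contrasts were NaCl against the solute control, PEG against the matric control, the difference of these responses, and the matric against the solute control. No term for slide was added, because slide is fixed by group for the stress contrasts and cannot be separated from the control groups.

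Before the data were examined, 21 gene lists matched on product names were fixed, but the files name genes only by tag, so 0 lists were tested, and no gene function is stated. Genes named in the text were the 2 with the largest rise and the 2 with the largest fall per contrast among called genes, with all stressed arrays beyond all controls (or all matric controls beyond all solute controls) except in the interaction contrast; for both stresses they were the 2 per direction with the largest smaller change. A run is a series of tags, with number gaps of at most 2, called in the same direction; only tag order was used, since genome coordinates are not used here. Runs of at least 5 genes were compared with 1000 permutations of the calls. The block of the control contrast joined runs with a median of at least 2-fold and gaps of at most 10 tags. Runs and the block were defined after the data were seen, and so was the check in which group means below the brightest reporter feature of the group were raised to it.

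The NaCl and PEG contrasts were also tested on simulated data with the real means and spreads and 200 changed genes among 4630. For NaCl, 56.8% of genes changed 1.3-fold, 80.4% changed 1.5-fold and 95.6% changed 2-fold were recovered, and for PEG 36.8%, 65.6% and 93.2%. On average 6 unchanged genes were called for NaCl and 7.4 for PEG. The simulation held no slide difference, no deviation shared by the genes of an array, no deviant array and fewer changes than were called. Its rates therefore do not cover these features of the real arrays.

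Alternatives were normexp background correction with an offset of 50, quantile and median scaling, other filters on dim probes, the brightest probe of each gene, the authors' values, other sets of arrays in the fit, pooled controls, replicate and array-row blocks, a mean-variance trend, array weights, a 2-fold threshold and each array left out. Normexp was run on the median spot and background intensity, the spot summary used here in place of the planned mean.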

Results

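Transcript levels were measured in Pseudarthrobacter (formerly Arthrobacter) chlorophenolicus A6, a soil actinobacterium, after a 30 min shock with either of 2 stresses that lower the water potential. NaCl lowered the solute potential to -1.5 MPa, and PEG8000, a large polymer that cells take up poorly, lowered the matric potential to -1.0 MPa. Each stress had a control culture of its own in the same medium. The 14 arrays analysed here were 4 solute controls, 4 NaCl arrays, 4 matric controls and 2 PEG arrays. Each array carried 13589 probes for 4632 named features, nearly all of them numbered locus tags of this genome, and 4630 features were tested. The files pair no tag with a gene name, so genes are given by tag only. All levels are log2 values relative to the 75th percentile of their array.

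The 75th percentile of the processed signal lay between 1730 and 3490 over the 14 arrays, and between 97.5% and 99.99% of the probes of an array were marked as well above background. Pairs of arrays of the same group correlated across genes at r = 0.989 to 0.998. The median SD of a gene between arrays was 0.14 in the solute controls, 0.11 under NaCl, 0.13 in the matric controls and 0.15 between the 2 PEG arrays. The number of arrays limited the precision, and the median standard error of a log2 change was 0.10 for NaCl and 0.12 for PEG. The solute arrays were on slide 1 and the matric arrays on slide 2, each slide with its own scan date, so each stress was compared with its control within a slide.

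The first comparison addressed the response to solute stress. With its probes averaged Achl_0518 had the largest rise under NaCl, from 1.14 ± 0.13 (SD, n = 4) in the controls to 3.95 ± 0.05 (SD, n = 4), a 7.03-fold increase (log2 change 2.81 ± 0.09 SE, limma adjusted p = 1.5e-10). Achl_3496 rose 6.32-fold, by 2.66 ± 0.10 SE (limma adjusted p = 3.8e-10). With the brightest probe of each gene the order changed: the largest rises were 2.99 for Achl_3496, 2.96 for Achl_2561 and 2.67 for Achl_0518, and Achl_2991 (-3.27) had a larger fall than Achl_2994 (-3.13). Achl_2994 fell by 3.20 on the log2 scale (SE 0.15, limma adjusted p = 3.6e-09), from -0.25 ± 0.34 to -3.44 ± 0.22 (SD, n = 4 each). Achl_1179 fell by 2.99 (SE 0.12, limma adjusted p = 5.4e-10). In each of these 4 genes all 4 NaCl arrays lay beyond all 4 controls.

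Genes with neighbouring tag numbers moved together under NaCl. Tags 2975 to 3003, among them Achl_2994, made up the longest run, with 29 consecutive tested genes that all fell and a median log2 change of -1.26. Tags 1210 to 1217 fell as a run of 8 genes with a median of -0.55. The longest rising runs, of 8 genes each, were tags 80 to 87, with a median of 0.81, and tags 3258 to 3265, with a median of 0.62. Permuted calls reached rising runs of up to 10 genes, so these 2 are no longer than chance can give, while falling runs reached at most 7. With the brightest probe the median of tags 2975 to 3003 was -0.73. Runs of at least 5 genes held 184 genes in 26 runs, against a mean of 5.95 genes and a highest value of 31 over 1000 permutations of the calls along the tags (permutation p = 0.001, one-sided, the smallest these permutations can give). Runs were chosen for description after the values were seen.

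NaCl changed 1566 of the 4630 features at an adjusted p under 0.05 in limma, 852 higher and 714 lower. Of these, 50 were higher and 59 lower by at least 2-fold. The direction went with the level of the gene, less so with normexp or quantile normalization and no less with median scaling. In the dimmest quartile of genes 228 rose and 44 fell, and in the brightest quartile 145 rose and 329 fell. The dimmest quartile had 87 and 69 with normexp background correction, 158 and 118 with quantile normalization and 366 and 56 with median scaling. The balance of directions was not stable: 712 were higher and 809 lower with normexp, 747 and 822 with quantile normalization, 800 and 814 with the authors' deposited values, 649 and 793 with pooled controls, and 276 and 408 with a replicate block. Single arrays turned it too, with 505 higher and 622 lower without NaCl replicate 4, 519 and 531 without NaCl replicate 3, and 553 and 595 without solute control replicate 1. With array weights the count was 2731.

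The second comparison addressed the response to matric stress. With its probes averaged Achl_1348 had the largest rise under PEG, from -1.75 ± 0.05 (SD, n = 4) to 1.35 ± 0.18 (SD, n = 2), an 8.55-fold increase (log2 change 3.10 ± 0.12 SE, limma adjusted p = 6.6e-09). Achl_0802 rose 7.05-fold, by 2.82 ± 0.14 SE (limma adjusted p = 2.0e-08). Their probes differed: with the brightest probe the changes were 2.14 for Achl_1348 and 1.69 for Achl_0802, below the 2.60 of Achl_0996. Achl_0754 and its neighbour Achl_0755 had the largest falls. Achl_0754 fell by 3.44 (SE 0.22, limma adjusted p = 1.7e-07), from 3.04 ± 0.18 (SD, n = 4) to -0.40 ± 0.06 (SD, n = 2), and Achl_0755 fell by 3.10 (SE 0.27, limma adjusted p = 2.4e-06). In each of these 4 genes both PEG arrays lay beyond all 4 controls.

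Tags 2976 to 3003 fell under PEG as well, as a run of 28 genes with a median log2 change of -1.37. Tags 4604 to 4613 fell as a run of 10 genes with a median of -1.60. The longest rising runs, of 7 genes each, were tags 3730 to 3736, with a median of 1.79, and tags 3260 to 3266, with a median of 0.65. Permuted calls also reached a rising run of 7 genes, and falling runs of at most 5. With the brightest probe the median of tags 3260 to 3266 was 0.36 and that of tags 4604 to 4613 was -1.03. Runs of at least 5 genes held 104 genes in 14 runs, against a mean of 0.26 genes over 1000 permutations (permutation p = 0.001, one-sided, the smallest these permutations can give).

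**Figure D1:**
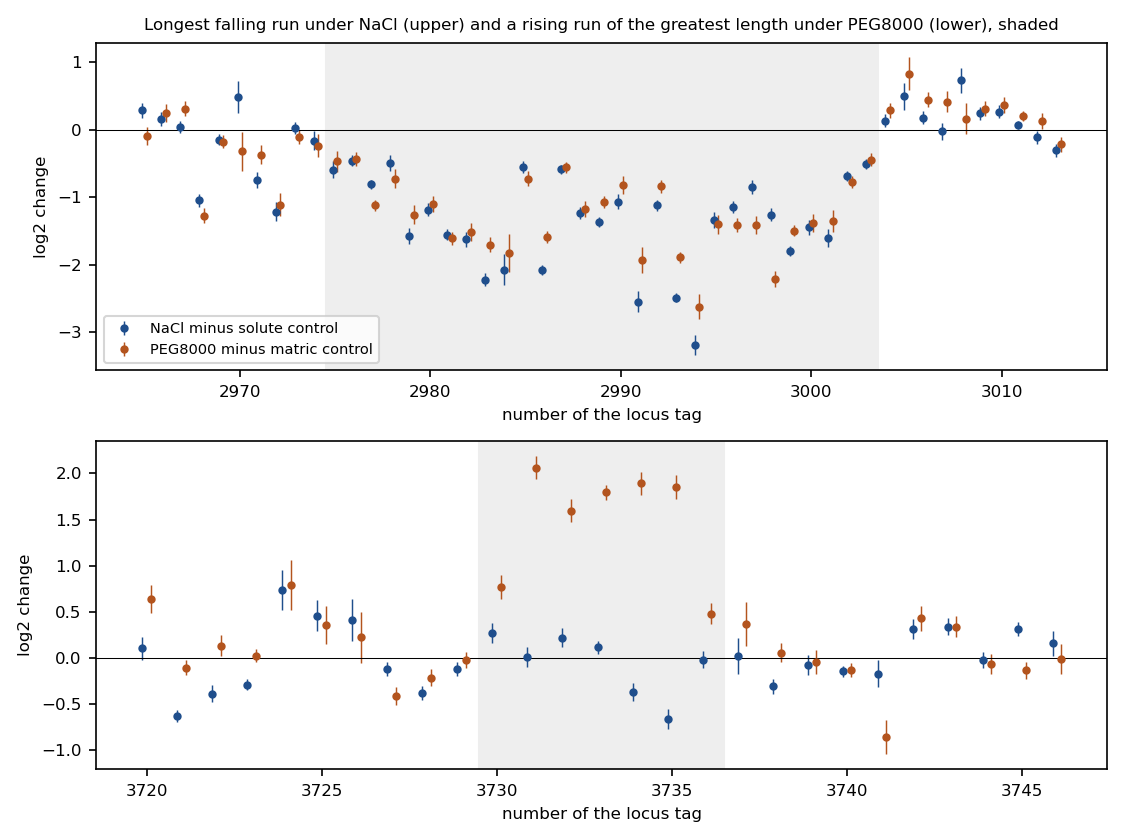
Log2 changes of neighbouring genes under NaCl (dark blue) and PEG8000 (brown), each against its own control, plotted against the number of the locus tag, with bars for the standard error and shading for the run. Upper panel, tags 2975 to 3003 lie below 0 under both stresses. Lower panel, tags 3730 to 3736 rose under PEG (median 1.79) with a median of 0.01 under NaCl. Of the 5 genes of tags 3731 to 3735, 2 were called lower under NaCl.

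PEG changed 770 of the 4630 features in limma, 470 higher and 300 lower, of which 49 were higher and 60 lower by at least 2-fold. In the dimmest quartile 129 rose and 10 fell (391 and 9 with normexp, 139 and 78 with quantile normalization), and in the brightest quartile 100 rose and 133 fell. The share of higher calls was 61.0%, and it was 71.7% with normexp background correction, 48.0% with quantile normalization and 47.6% with the authors' deposited values. The count rested on 2 arrays: without PEG replicate 2 it was 480, with 206 higher and 274 lower, and without PEG replicate 1 it was 1083, with 872 higher and 211 lower. With a replicate block it was 194, and the balance turned, with 80 higher and 114 lower. That block leaves fewer residual degrees of freedom, and only matric controls numbered like a PEG array enter its PEG change. It was 380 when fitted on slide 2 alone, 450 with array weights, 425 with the brightest probe of each gene (211 higher and 214 lower) and 1243 with normexp.

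**Figure D2:**
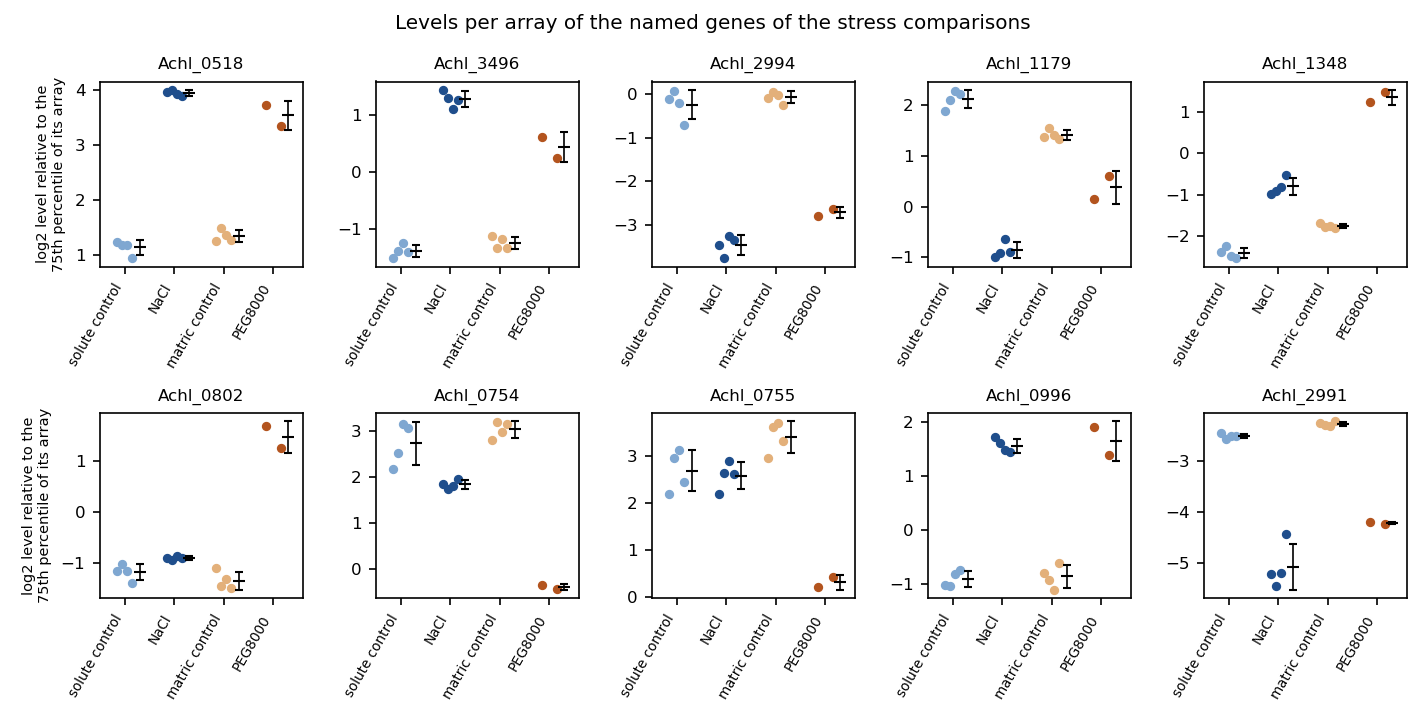
Levels of the 10 genes named for the NaCl and PEG comparisons and for both stresses, 1 point per array, as log2 relative to the 75th percentile of the array, in the solute controls, NaCl, matric controls and PEG8000, with the mean and SD of each group beside its points. Achl_0518 and Achl_0996 rose under both stresses, and Achl_0802 rose and Achl_0755 fell under PEG with NaCl arrays near their controls. For Achl_0802 all NaCl arrays lay slightly above all solute controls.

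The third comparison set the 2 responses side by side, as the design of the study asks. Achl_0996 rose by 2.46 ± 0.13 SE under NaCl and by 2.495 ± 0.16 SE under PEG (limma adjusted p = 1.0e-08 and 1.7e-07). Achl_0518 rose by 2.81 ± 0.09 SE and 2.20 ± 0.11 SE (limma adjusted p = 1.5e-10 and 3.2e-08). Achl_2994 fell by 3.20 under NaCl and by 2.62 under PEG, and Achl_2991, from the same run of tags, fell by 2.55 and 1.94. Under NaCl Achl_2991 lay at -5.07, below the brightest reporter feature (-4.58), so the size of its fall is uncertain: over the alternatives it ranged from -3.27 to -1.86 under NaCl and from -2.55 to -1.45 under PEG. Within tags 2975 to 3003, 28 of the 29 genes that fell under NaCl also fell under PEG. The control arrays of the 2 comparisons were different arrays, so the overlap holds no shared control.

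A total of 461 features changed in the same direction under both stresses. The 229 that rose in both compare with 86.5 for independent lists of these sizes (exact one-sided hypergeometric p = 1.2e-57), and the 232 that fell in both compare with 46.3 (exact one-sided hypergeometric p = 6.5e-140). These p-values take genes as independent, which runs of neighbouring genes are not. Both contrasts also use the same estimate of a gene's spread, which favours calls in both. The rise of dim genes under both stresses, whose cause stays open, can add to the genes that rose in both. Another 14 changed in opposite directions, against 127.7 for independent lists. The log2 changes correlated across genes at r = 0.649 (Spearman rho = 0.631), and genes are not independent replicates. The split of the shared features rested on single PEG arrays, with 443 higher and 167 lower without PEG replicate 1 and 108 and 201 without PEG replicate 2. It was 225 and 334 with quantile normalization and 245 and 355 with the authors' deposited values. The shared count was 139 with a replicate block, with 41 higher and 98 lower, 219 with the brightest probe and 257 with each contrast fitted on its own groups, and r was 0.450 without PEG replicate 2. The overlap of independent lists also falls when the lists are shorter, so these counts alone do not show a smaller excess over it.

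**Figure D3:**
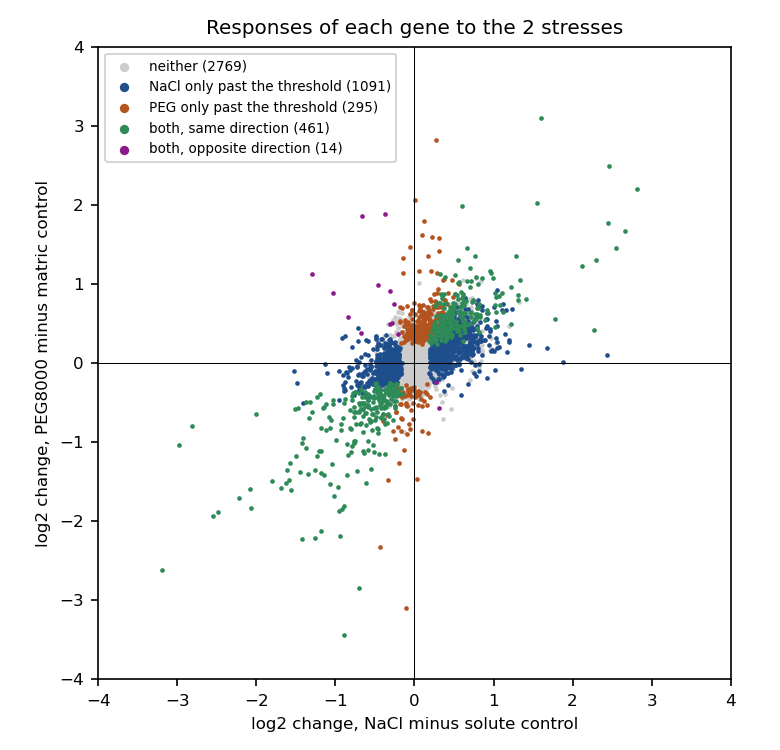
Log2 change of each of the 4630 features under NaCl (x axis) and under PEG8000 (y axis), each against its own control, coloured by the comparison in which it passed an adjusted p of 0.05. The 461 features that changed in the same direction lie along the diagonal (r = 0.649 over all features), and 14 changed in opposite directions.

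The responses of some genes differed between the stresses, which the interaction contrast tested directly. Achl_0755 differed by 3.00 ± 0.34 SE (NaCl minus PEG, limma adjusted p = 0.00014), with a change of -0.10 ± 0.22 SE under NaCl against -3.10 under PEG. Achl_0754 differed by 2.54 ± 0.28 SE (limma adjusted p = 0.00011), with -0.90 under NaCl against -3.44 under PEG. Achl_0802 differed by -2.54 ± 0.18 SE (limma adjusted p = 1.4e-06), with 0.28 under NaCl, which missed the threshold (limma adjusted p = 0.069). All NaCl arrays of Achl_0802 still lay above all its solute controls. Achl_3735 differed by -2.52 ± 0.17 SE (limma adjusted p = 1.4e-06), falling by 0.67 under NaCl and rising by 1.86 under PEG. Its neighbours, tags 3731 to 3735, differed as a run of 5 genes with a median of -2.05, and tags 1179 to 1183 fell further under NaCl (median -2.003) than under PEG (median -0.64), also in all 5 genes. Permuted calls also reached runs of 5 genes in this contrast, so the length of a single run is within chance. Together the 2 runs held 10 genes, against a highest value of 5 over 1000 permutations (permutation p = 0.001, one-sided, the smallest possible).

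The interaction passed the threshold in 226 features, 78 with the NaCl response above the PEG response and 148 below it. Of the 148, 71 fell under NaCl and were not called under PEG, 45 rose under PEG and were not called under NaCl, and 12 fell under NaCl and rose under PEG. The 2 stresses also differed in their size in MPa, so these differences are between the treatments as applied. The NaCl response lay above in 34.5% of the calls, in 45.2% with quantile normalization, in 45.9% with median scaling, in 46.6% with the authors' deposited values, in 49.1% without PEG replicate 2 and in 24.6% with normexp. With the brightest probe the majority turned, with 77 above and 72 below (51.7%). The count was 33 with a replicate block, 48 at 2-fold and 149 with the brightest probe. It was 135 without NaCl replicate 3 and 147 without NaCl replicate 2. With quantile normalization it was 345, with the authors' values 393, with normexp 439, and with normexp and quantile normalization together 454. Pooled controls cancel from this contrast, so the 1024 calls there compare NaCl with PEG arrays directly, across the slides.

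The last comparison measured how the unstressed cultures of the 2 experiments differed. Achl_4209 was higher in the matric controls by 7.14 ± 0.12 SE on the log2 scale (limma adjusted p = 4.3e-14), and Achl_4212 was higher by 5.41 ± 0.09 SE (limma adjusted p = 4.3e-14). In the solute controls both lay near the reporter features, at -5.85 and -5.92 against a reporter median of -6.12, so no fold is given. With those levels raised to the brightest reporter feature the differences were 6.06 and 4.26, and with normexp and quantile normalization 5.63 and 3.57. Both lie in a block of neighbours, tags 4206 to 4345, in which 126 of 140 genes were called higher in the matric controls, with a median difference of 1.55. On the solute controls 77 of the 140 were no brighter than the brightest reporter feature, and with levels raised to that feature the median was 0.83. The median level of the block was -5.03 in the solute controls and -4.82 under NaCl, against -3.20 in the matric controls and -2.97 under PEG. Smaller differences the other way included Achl_3256 at -1.16 ± 0.14 SE (limma adjusted p = 6.4e-05) and Achl_1979 at -1.09 ± 0.14 SE (limma adjusted p = 0.00011).

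**Figure D4:**
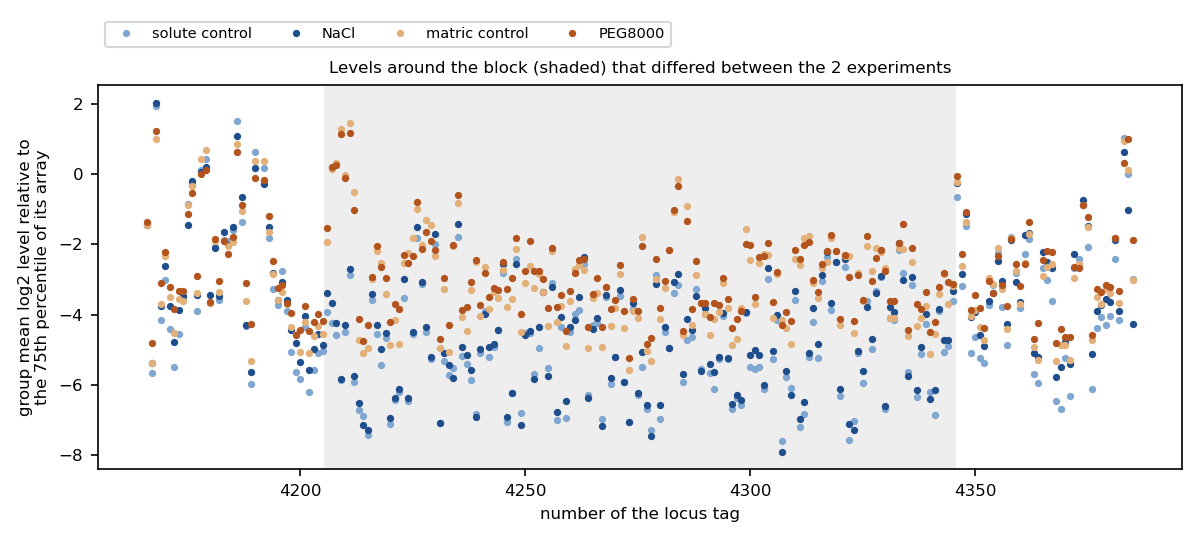
Mean log2 level of each group, relative to the 75th percentile of its array, for the genes of tags 4206 to 4345 (shaded) and their neighbours, against the number of the locus tag. Within the block the solute controls and NaCl (blue, block medians -5.03 and -4.82) lie below the matric controls and PEG8000 (orange and brown, -3.20 and -2.97).

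In all, 1536 of 4630 features differed between the control groups, 1186 higher and 350 lower in the matric controls, and 161 of those higher and 3 of those lower differed by at least 2-fold. Of the 161, 101 lay in tags 4206 to 4345 and 60 outside them. This contrast cannot be told apart from slide and scan date, since each control group lay on a slide of its own. The median over all features was 0.14, and -0.02 with quantile normalization, which changed the share of higher calls from 77.2% to 43.0%. That share was 63.2% with median scaling and 44.2% with the authors' deposited values. With the brightest probe the majority turned as well, with 741 higher and 932 lower, and 719 of the 1536 calls were lost. Without matric control replicate 1 the count was 1060, with 732 higher and 328 lower.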

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

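The swap test of the solute control below was chosen after its result was seen; the test for a partial stress response was not.

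In the interaction contrast 226 features responded differently to NaCl and PEG, and the tested differences (NaCl minus PEG) with probes averaged were largest for Achl_0755 at 3.00, Achl_0754 at 2.54, Achl_0802 at -2.54 and Achl_3735 at -2.52 on the log2 scale. With the brightest probe Achl_3734 passed the last 2, at -2.53. These genes stood out because the effects of the 2 stresses differed in a test of the difference itself.

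Among 57 groups of 4 arrays tested for an array far from the others with Dixon's ratio, 4 stood out, against 2.85 by chance at 1 in 20. The groups covered levels of the named genes and measures of array quality. All 4 were among the quality measures and none among the gene levels, so 2.85 is too high a figure for the quality measures alone. The 75th percentile and the median describe the same signal and do not count as separate outliers. The 75th percentile (ratio 0.866) and the median (ratio 0.867) of the signal were low in solute control replicate 2, at 2286 and 621. Matric control replicate 3 had 99.2% of probes well above background (ratio 0.9897) against 99.9% in the other matric controls.

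Solute control replicate 4 had a residual SD of 0.23 on the log2 scale against 0.13 to 0.14 in the other solute controls (ratio 0.875). A swap with a NaCl array is argued against, since 0 NaCl arrays correlated better with the controls than with their own group, and this control correlated at 0.991 with its group against 0.977 with NaCl. A partial response to stress is argued against too, since its deviation from another control correlated at -0.0093 (-0.09 to 0.08 over 3 choices of control) with the NaCl response against the remaining controls. Differences in RNA preparation, hybridisation or the culture itself stay open, and no other biological explanation was tested. Without this array NaCl changed 1508 features and the interaction 320.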

How the results depend on the processing

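The array-row block, the filter against reporters and the omission of the block of tags were added after the data were seen. The 22 named gene and contrast pairs kept direction and threshold in all 628 alternative values, though sizes and order changed with the brightest probe. These pairs were picked on the same arrays as the largest changes, so the count says little about other calls. Leaving out an array of the other experiment also cannot alter the size of a NaCl or PEG change. NaCl changed 1566 features, 684 with a replicate block, 2731 with array weights and 109 at 2-fold; leaving out an array gave 1050 to 1817. PEG changed 770, 1243 with normexp, 425 with the brightest probe, 380 on its own groups, 194 with a replicate block, 450 with array weights and 109 at 2-fold; leaving out an array gave 480 to 1083. The interaction held 226, 439 with normexp, 345 with quantile normalization, 454 with both and 393 with the authors' values. It held 149 with the brightest probe, 33 with a replicate block and 48 at 2-fold, and leaving out an array gave 135 to 320. The 1024 calls with pooled controls are no interaction count, since the controls cancel and NaCl is compared with PEG directly. The control contrast held 1536, 164 at 2-fold and 1389 without the block of tags; leaving out an array gave 1060 to 1800. Its 1673 calls with the brightest probe shared 817 with the 1536, and its 1770 with quantile normalization shared 992. The 461 shared features became 219 with the brightest probe, 257 on own groups, 139 with a replicate block and 42 at 2-fold. Shorter lists also share fewer genes by chance. The correlation of 0.649 was 0.260 with pooled controls and 0.450 to 0.697 with an array left out. Pooling carries the difference between the control groups into the NaCl and PEG responses with opposite signs. Unchanged genes gave 0.256 with pooled controls in simulation. That simulation held no such difference, so its likeness to 0.260 says nothing about a shared response. Except for the 2-fold threshold and for fewer arrays, the cause was not tested. The replicate block leaves fewer residual degrees of freedom than the main fit. Matric controls without a PEG array of the same number also drop out of its PEG change, so fewer calls with it are partly built in. With a PEG array left out the lone array is assumed to vary like the other groups. The 8 runs named for NaCl and PEG kept the sign of their median, but with the brightest probe tags 2975 to 3003 moved from -1.26 to -0.73 under NaCl, tags 3260 to 3266 from 0.65 to 0.36 and tags 4604 to 4613 from -1.60 to -1.03 under PEG.

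Replicate numbers were not taken as pairing the arrays: deviations of same-numbered arrays correlated at -0.16, -0.03, 0.03 and -0.25 in the solute and -0.68 and -0.24 in the matric experiment, and no NaCl array correlated best with its own number. The deviations of the 2 PEG arrays mirror each other, so the -0.68 means that matric control 1 deviated together with PEG replicate 2. The SD of the difference between those arrays was 0.373, against 0.378 between the 2 PEG arrays, though the PEG arrays correlated more closely (0.989 against 0.984). The fit takes all arrays as independent. Slide and scan date as blocks add no term to the stress contrasts and leave the control contrast without an estimate, so they were not run, nor were the gene lists with camera or fry. Signal over background limits genes near the reporter features.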

Other observations

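The tests of slide brightness, of the reporter features and of the negative control spots below, and all runs and features described here, were chosen after the values were seen; the test of probe agreement was not.

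Other groups of neighbouring genes moved under a single stress or under both, though permuted calls reached rising runs of up to 10 genes for NaCl and 7 for PEG and falling runs of 5 for PEG. Tags 3685 to 3691 rose under NaCl with a median log2 change of 0.99, and 6 of these 7 genes also rose under PEG. Tags 3783 to 3787 rose under PEG with a median of 1.17 against 0.09 under NaCl, and the interaction passed in 3 of the 5. Tags 3911 to 3915 rose under PEG with a median of 0.70 against 0.12, with the interaction in 4 of 5. Tags 3480 to 3484 rose under NaCl with a median of 0.83 against 0.20 under PEG, with the interaction in 4 of 5. Tags 1985 to 1989 fell under PEG with a median of -2.19 against -0.59 under NaCl, with the interaction in 2 of 5.

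Of the 3 tags with an R before the number, Achl_R0015 and Achl_R0016 did not pass the threshold under either stress, and Achl_R0017 fell by 0.71 ± 0.16 SE under NaCl (limma adjusted p = 0.0051) with 0.27 ± 0.20 SE under PEG (limma adjusted p = 0.36). Its interaction was -0.98 ± 0.26 SE (limma adjusted p = 0.044).

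Tags 4206 to 4345 were dimmer in both solute groups than in both matric groups. A brightness or scaling difference between slides was examined with genes outside the block matched on level. These differed between the controls by a median of 0.22 (0.17 to 0.30 over 1000 matched sets), which measures a shift common to genes of that level. The block's median was 1.55, or 0.83 with levels raised to the brightest reporter feature. Because the block was built from runs called higher in this same contrast, with medians of at least 2-fold, a larger median than in unselected genes was built in. The comparison alone therefore does not decide on a slide difference. Absence of transcript from part of the block in the solute cultures is consistent with the agreement of probes: the correlation of probe pairs of a gene was -0.071 over the block on the solute controls, below the 0.18 to 0.37 of level-matched sets, and 0.25 on the matric controls. On the solute controls 77 of the 140 genes were no brighter than the brightest reporter feature (-4.77). On the matric controls 5 were no brighter than the brightest there, which lay lower, at -5.06. The reporter feature Achl_GFP_1 itself differed between the controls, by -0.56 (limma adjusted p = 0.031). Absence does not hold for every member: tag 4230 lay at -1.99 on the solute and -2.33 on the matric controls. Tag 4333 lay at -2.16 and -2.10 and tag 4317 at -2.35 and -2.50, all above the brightest reporter feature on the solute controls. Whether parts of the segment were missing from the DNA of those cultures or present and silent stays open, since only RNA was measured and slide, scan and experiment coincide.

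Genes in the dimmest quartile had a median log2 change of 0.28 under NaCl and 0.32 under PEG. For NaCl a candidate explanation is non-specific signal, since the 7 reporter features had a median change of 0.27, upward in 6, though no tested reporter passed the threshold by itself and the negative control spots, another measure of non-specific signal, did not rise relative to the 75th percentile (-0.26, SE 0.13), while normexp lowered the quartile's median to 0.09. For PEG the reporters did not rise, with a median of -0.045, while the quartile's median was 0.31 with normexp. The standard error of the reporters' mean (0.15) is over features on the same arrays and leaves out the error that an array gives to all of them. The median change of all features was 0.002 without PEG replicate 2 and 0.198 without PEG replicate 1. With 2 PEG arrays the reporters therefore cannot decide on non-specific signal. Quantile normalization brought the quartile's medians to 0.05 under NaCl and 0.07 under PEG. A shift relative to the 75th percentile and a true rise of weakly transcribed genes both stay open.

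For the counts of NaCl and of the control contrast, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many genes in each case. The real counts were 1566 and 1536, and the highest of the other splits gave 0 in both. Chance assignment of arrays is thus argued against only as far as 35 splits allow. The other splits mix arrays of both groups, which widens the spread within a group, so few calls there are built in. For the control contrast the split cannot be told apart from slide and scan date.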
